A study of Mus musculus with 28 samples.

How the data were processed

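PolyA RNA of cultured mouse cardiac fibroblasts and myofibroblasts was measured in 28 libraries. The groups were the 8 combinations of culture (fibroblast or myofibroblast), oxygen (1% or 21%) and siRNA (Adam17 or control), as the labels name them, with 4 libraries per hypoxia group and 3 per normoxia group. Per the labels, the cells were wild type, pooled from male and female animals, used at passage 1 and kept in medium with 2% serum, and all libraries belonged to 1 batch. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

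Per the file headers, the authors ran kallisto 0.44.0 on paired-end reads against an index of 116912 cDNA sequences of mouse build GRCm39, and the deposited tables hold kallisto's estimated counts and effective lengths per transcript, not normalized. The libraries held 19762646 to 30641389 read pairs (median 23101371.5), of which 88.7% to 93.1% were pseudoaligned. Each library came with a second table of the same quantities that differed by at most 0.499 of a count, which was used as an alternative. No trimming or filtering of reads was given in the sources used here.

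Estimated counts were summed to genes by transcript identifier. Gene matches, names and 3′ untranslated regions came from GENCODE M21, made for an older genome build than GRCm39. Of the transcripts, 115494 matched a gene and 1418 did not, and the latter held 0.488% to 0.623% of the counts of a library and stayed out of library sizes and tests. The index lacks Xist, Tsix, mt-Rnr1 and mt-Rnr2, so the sex-linked list rests on 4 Y-linked genes. Sums over 35757 genes were rounded to whole numbers. Genes with near-identical copies share reads, which kallisto splits by an estimate, so values of paralogs such as Ly6a and Ly6c1, the Ifit, Oas and Apol9 genes, Serpina3g and the ribosomal protein and metallothionein genes are uncertain. The tables give no strand, so overlapping and antisense genes are uncertain too.

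Tests used edgeR 4.0.16 in R 4.3.3, with the default expression filter by group, which left 14725 genes, TMM scaling, and a robust quasi-likelihood fit of all 28 libraries with 1 coefficient per group, so that groups shared 1 estimate of the spread. The 10 comparisons of 2 groups were Adam17 against control siRNA in each of the 4 settings, hypoxia against normoxia in each of 4, and myofibroblasts against fibroblasts among control cultures in each oxygen level. The 5 differences of effects were tested as contrasts of the same fit. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Log2 changes are edgeR's, with standard errors, and levels are counts scaled to library size (CPM), given as mean and SD over libraries. Log2 CPM used a prior count of 2. The common biological coefficient of variation was 0.0484. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

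The 36 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The lists were collagens, matrix glycoproteins, proteoglycans, collagen crosslinking and processing, matrix proteases, protease inhibitors, contractile myofibroblast genes, the TGF-beta pathway, angiogenic factors, angiogenesis inhibitors, HIF target genes, glycolysis, oxidative phosphorylation, ADAM17 substrates, the ADAM family and ADAM17 regulators, and EGFR and immediate early genes. The others were cytokines and chemokines, NF-kappaB targets, interferon-stimulated genes, cell cycle, p53 targets and senescence, apoptosis, the unfolded protein and integrated stress response, cholesterol synthesis, NRF2 and antioxidant genes, YAP/TEAD targets, integrins and focal adhesion, fibroblast identity, ribosomal proteins, mitochondrial transcripts, and markers of endothelial cells, macrophages and leukocytes, cardiomyocytes, smooth muscle and pericytes, and epicardial, mesothelial and Schwann cells, with sex-linked transcripts. Lists of at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list with all other genes. The alternatives were a correlation estimated per list and fry, which asks whether a list's genes move on balance without comparing them with other genes.

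Adam17 was named first. In each comparison of 2 groups the 5 largest rises and 5 largest falls were named among protein-coding genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. In each described list up to 4 members past the threshold with the largest changes could be named, or the 1 or 2 most abundant members where none passed. Described lists had a camera call or at least 3 members past the threshold, with the matrix, angiogenesis, ADAM17 and contractile lists counted in each comparison of 2 groups whatever they showed, and some of the other qualifying lists of a comparison are given here by their camera result or left out for length. For differences of effects, the 5 genes with the smallest adjusted p were named. Genes under this rule with very few counts in 1 group or a library at 0 are given as counts per library. Genes compared across the plots, the levels of genes named in another comparison, and the genes shared by all 4 silencing comparisons were chosen after their values were seen.

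The alternatives were DESeq2 1.42.0, relative log expression size factors, no filter beyond 1 count, a filter of 1 CPM in at least 7 libraries, offsets from effective transcript lengths, a fit of only the groups compared, the replicate number as a block, the second table of each library, and leaving out each library in turn. A count that leaves out genes differing between the normoxic control cultures was chosen after seeing the data. Every pair of replicates differed by more than sampling noise, with a chi-square of 2.53 to 8.17 per degree of freedom over genes with a summed count of at least 20, so all libraries were counted.

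The steps were tested on simulated data made from the means and library sizes of these samples, run over 14725 genes. For Adam17 siRNA in hypoxic fibroblasts, edgeR recovered 59.7% of the genes changed 1.25-fold, 83.6% of those changed 1.5-fold and 90.9% of those changed 2-fold, with 5 false calls among 161. For normoxic fibroblasts the shares were 50.7%, 77.6% and 95.5%, with 9 false calls among 158. Short words in 3′ untranslated regions were counted in 13929 of 14013 tested protein-coding genes, and a simulated change of 0.2 in the genes with 1 word ranked that word at 1.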

Results

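PolyA RNA was sequenced from cardiac fibroblasts of wild-type mice, pooled from male and female animals, at passage 1. The cells were cultured as fibroblasts or as myofibroblasts, the contractile and matrix-producing form that fibroblasts take on after injury. Each culture received small interfering RNA (siRNA) against Adam17, which codes for a membrane protease that sheds growth factors, cytokines and receptors, or a control siRNA, and was kept at 21% oxygen (normoxia) or 1% oxygen (hypoxia). The 8 groups held 28 libraries, 4 in each hypoxia group and 3 in each normoxia group. The libraries held 18161595 to 28096019 estimated counts (median 21136134), and 14725 genes were tested. The title of the study concerns ADAM17 in fibroblasts after myocardial infarction, tissue stiffness and vascularization, so matrix, contractile and angiogenic genes are given in each comparison of 2 groups.

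Adam17 itself was lower in every library with Adam17 siRNA than in any library with control siRNA. In hypoxic fibroblasts levels in counts scaled to library size (CPM) were 23.1 CPM ± 0.95 (SD, n = 4) with Adam17 siRNA and 83.7 CPM ± 2.8 (n = 4) with control siRNA, 72.4% lower. The reduction was 76.4% in hypoxic myofibroblasts, 72.6% in normoxic fibroblasts and 74.0% in normoxic myofibroblasts, with log2 changes of -2.08, -1.87 and -1.94 and adjusted p of 1.7e-31, 1.86e-27 and 5.49e-28. Among the control groups, Adam17 was 77.1 CPM ± 0.78 (n = 3) in normoxic and 90.9 CPM ± 3.0 (n = 4) in hypoxic myofibroblasts, a rise of 0.24 on the log2 scale with hypoxia (adjusted p = 1.91e-05).

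**Figure D1:**
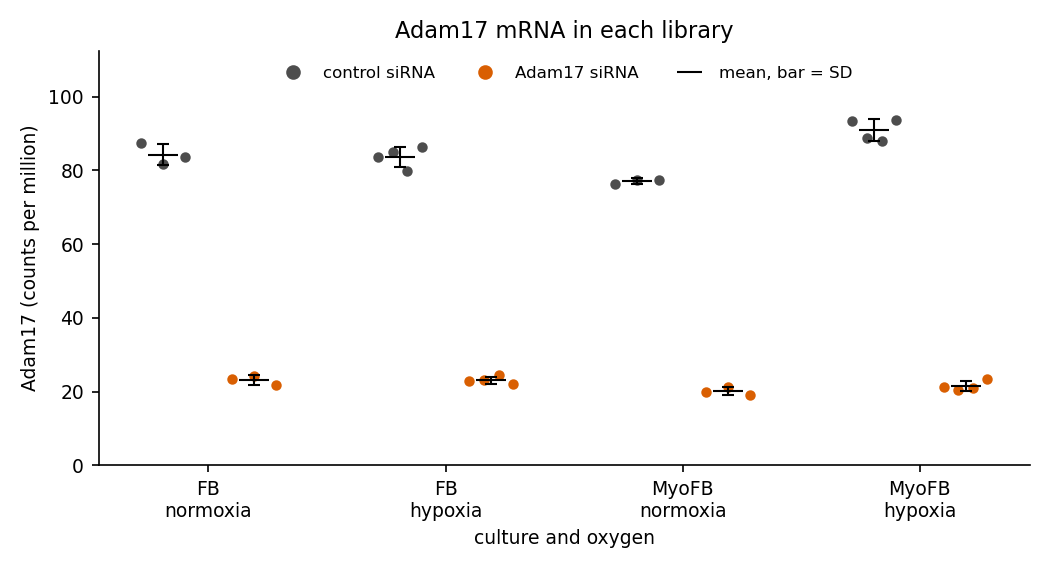
Adam17 in CPM for each library (points), with the mean and SD of each group (black), by culture (FB fibroblast, MyoFB myofibroblast), oxygen and siRNA. The group means were 20.1 to 23.1 CPM with Adam17 siRNA and 77.1 to 90.9 CPM with control siRNA.

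Over all tested genes, the first principal component held 27.7% of the variance of log2 CPM and the second 18.1%. The fibroblast and myofibroblast groups lay apart in normoxia, and the hypoxic control siRNA fibroblasts lay nearest to the hypoxic myofibroblasts. Ltbp2, which codes for a microfibril-associated protein, stood at 867 CPM ± 11.8 (SD, n = 4) in hypoxic control fibroblasts, at 84.2 CPM ± 10.4 to 111 CPM ± 7.7 in the other 3 fibroblast groups, and at 922 CPM ± 40.9 to 1089.8 CPM ± 19.1 in the 4 myofibroblast groups. Over 5198 genes that differed between the normoxic control cultures, the effect of Adam17 siRNA had a slope of -0.54 on that difference in hypoxic fibroblasts and -0.06 in hypoxic myofibroblasts, with no library in common and over genes that are not independent replicates.

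**Figure D2:**
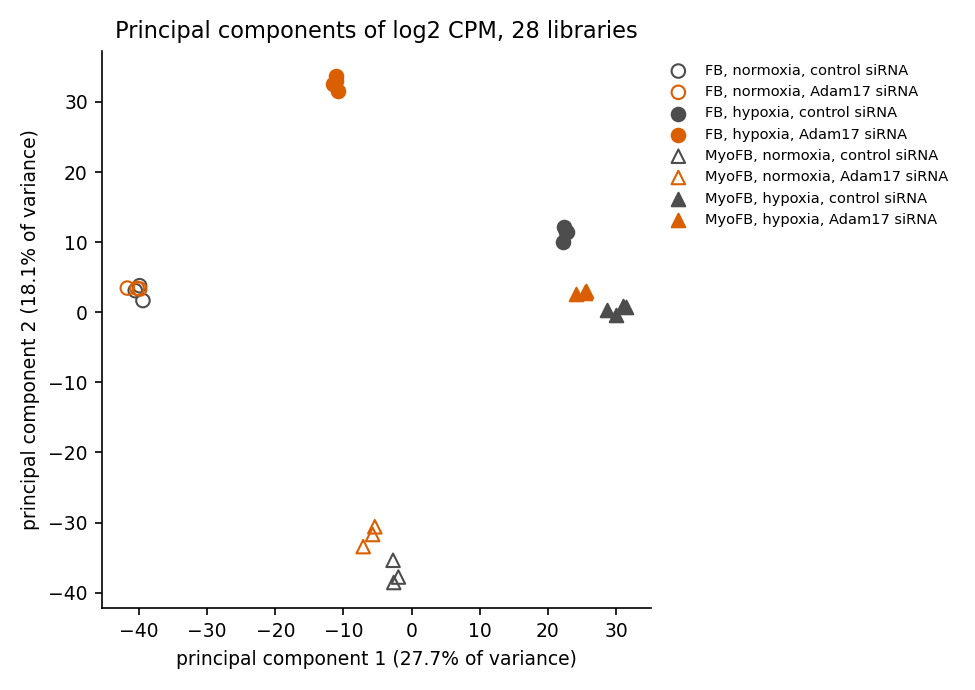
The first 2 principal components of log2 CPM over 14725 genes, with their shares of variance (27.7% and 18.1%) on the axes. Each point is 1 of the 28 libraries, with circles for fibroblasts (FB), triangles for myofibroblasts (MyoFB), filled symbols for hypoxia and orange for Adam17 siRNA.

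In hypoxic fibroblasts, Adam17 siRNA was compared with control siRNA for matrix, contractile and angiogenic genes. Among matrix genes, Postn, a matricellular protein of activated fibroblasts, stood at 1707 CPM ± 27 (SD, n = 4) with Adam17 siRNA and 4224 CPM ± 26.0 (n = 4) with control siRNA, and Ltbp2 at 104 CPM ± 3.8 and 867 CPM ± 11.8. Timp1, an inhibitor of matrix metalloproteinases, fell from 589.5 CPM ± 24.7 to 233 CPM ± 2.6, while Mmp13, a collagenase, rose from 0.819 CPM ± 0.34 to 7.60 CPM ± 0.62. Acta2, the smooth muscle actin of myofibroblasts, fell by 0.82 on the log2 scale (SE 0.075), from 2338 CPM ± 59.1 to 1326 CPM ± 97.8. Among secreted angiogenic factors, Vegfa did not pass, at 797 CPM ± 18.1 and 799 CPM ± 10.7. Rises were measured for Vegfd from 168 CPM ± 7.1 to 425 CPM ± 17.4, Adm, a vasodilator peptide, from 165 CPM ± 4.6 to 403 CPM ± 6.2, and Fgf7 from 6.38 CPM ± 0.31 to 15.6 CPM ± 0.51.

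By gene list in this comparison, 12 of 21 tested collagens fell and 5 rose (12 and 6 adjusted over the list alone), among them Col8a2 (log2 change -2.34, SE 0.141) and Col6a3 (-1.43, SE 0.056). Of 28 matrix glycoproteins 16 fell and 7 rose, and of 20 collagen crosslinking genes 13 fell and 4 rose, the same counts adjusted over the list alone. There were falls of Cilp (-3.01), Thbs1 (-0.97), the lysyl oxidases Loxl3 (-1.21) and Loxl4 (-0.90), and Tgm2 (-0.72). Contractile genes gave 15 falls and 2 rises of 20 (16 and 2 adjusted over the list alone), with Cnn1 (-1.19) and Tagln (-0.94) beside Acta2. Angiogenic factors gave 11 rises and 3 falls of 25 by either adjustment. Cholesterol synthesis genes, which SREBP factors switch on together, gave 19 rises and 1 fall of 23 by either adjustment. Insig1 stood at 334 CPM ± 13.6 against 205 CPM ± 3.6 (SD, n = 4 each). Genes of the unfolded protein and integrated stress response gave 20 falls and 1 rise of 25 (21 and 1 adjusted over the list alone), with the chaperone-linked Creld2 (-0.51) and Manf (-0.46). Oxidative phosphorylation genes gave 25 falls of 29 and ribosomal protein genes 23 falls of 25 (25 and 24 adjusted over the list alone), with Atp5g1 (-0.54) and Rps23 (-0.27). Interferon-stimulated genes gave 12 rises of 29 by either adjustment, with Zbp1 (1.36) and Oas2 (1.30). For signalling, 13 EGFR and immediate early genes rose and 3 fell of 27 (16 and 3 adjusted over the list alone), with Fos (1.21), Dusp1 (1.06) and Spry4 (1.30). In the same cells 10 YAP/TEAD targets rose and 5 fell of 20 by either adjustment, with Ccnd1 (1.58). Of 32 ADAM17 substrates, 15 rose and 6 fell (18 and 7 adjusted over the list alone), led by a fall of the membrane chemokine Cx3cl1 (-2.06) and a rise of Il6ra (1.37). Of 18 ADAM family genes and ADAM17 regulators, 8 rose and 4 fell by either adjustment, with Adam33 (1.32) and Adam23 (0.81).

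Among the remaining lists in hypoxic fibroblasts, proteoglycans gave 5 rises and 9 falls of 17 by either adjustment, with Cspg4 (-2.22) and Prelp (1.34). Matrix proteases gave 8 and 8 of 21 (9 and 8 adjusted over the list alone), with Adamts5 (1.01) beside Mmp13. TGF-beta pathway genes gave 8 rises and 11 falls of 22 (8 and 12 adjusted over the list alone), with Id1 (2.02) and Pmepa1 (-1.12). Cytokines and chemokines gave 7 rises and 6 falls of 20 (8 and 6 adjusted over the list alone), with the monocyte chemokine Ccl7 (1.66) and Il33 (-1.57). NF-kappaB targets gave 7 and 3 of 20 by either adjustment, with Icam1 (0.60) and the prostaglandin synthase Ptgs2 (-2.35). Fibroblast identity genes gave 7 rises and 8 falls of 20 by either adjustment, with the receptor Pdgfra (0.87) and the transcription factor Meox1 (-2.35). Endothelial markers gave 6 rises and 1 fall of 16 by either adjustment, with Ly6c1 (2.18). Protease inhibitors rose in 3 and fell in 3 of 8 and angiogenesis inhibitors in 9 and 4 of 17, by either adjustment. None of the lists in this paragraph had a camera call.

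Camera tested whether the genes of a list moved more than other genes, and each pair of values in parentheses gives its adjusted p with a preset correlation of 0.01 and then with an estimated correlation between genes. It called collagens (0.00076 and 0.38), matrix glycoproteins (0.00064 and 0.37), crosslinking (9.2e-06 and 0.27), contractile genes (8.5e-07 and 0.27), angiogenic factors (0.00076 and 0.16), cholesterol synthesis (3.2e-11 and 0.16), the unfolded protein response (3.7e-09 and 0.16) and oxidative phosphorylation (5.3e-07 and 0.27). The other calls were ribosomal proteins (1e-07 and 0.37), interferon-stimulated genes (0.00052 and 0.53), EGFR genes (0.016 and 0.36), YAP/TEAD targets (0.027 and 0.38) and the ADAM family (0.027 and 0.27). With an estimated correlation each of these calls ended in this comparison, and ADAM17 substrates had no call (adjusted p = 0.13). The largest rises were Mmp13 (log2 change 3.19, SE 0.198), the neutrophil chemokine Cxcl5 (3.18, SE 0.136), the imprinted gene Peg10 (2.36, SE 0.046), Galnt18 (2.36) and Scara5 (2.34). Falls were led by the chemokine Ccl17 (-4.30, SE 0.104), Padi4 (-3.63), Olfm2 (-3.35), the retinoic acid binding protein gene Crabp2 (-3.11) and Ltbp2 (-3.06, SE 0.048). Across all genes 5939 passed, 2896 higher and 3043 lower, of which 295 and 293 changed by more than 2-fold. Between these groups 2 of 18 macrophage and leukocyte markers rose and 7 fell by either adjustment, with Adgre1 (-0.48) and C1qa (-0.40) lower. Also, 2 of the 4 tested Y-linked genes rose, Ddx3y by 0.36 and Eif2s3y by 0.13. Eif2s3y lost its call with length offsets, and, at 0.11, without the first control siRNA or the fourth Adam17 siRNA library. Of the genes that passed and also differed between the normoxic control cultures, 89.5% of 3265 went toward the fibroblast level with Adam17 siRNA, 1537 of them lower and 1384 higher, where 552 and 497 were expected from the counts alone.

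In hypoxic myofibroblasts, Adam17 siRNA changed neither Ltbp2 nor Acta2 past the threshold: Ltbp2 stood at 922 CPM ± 40.9 (SD, n = 4) with Adam17 siRNA and 945 CPM ± 19.9 (n = 4) with control siRNA, and Acta2 at 1496 CPM ± 138 and 1508 CPM ± 75.1. Cholesterol synthesis genes rose in 20 of 23 by either adjustment, with Insig1 at 202 CPM ± 7.9 against 143 CPM ± 7.2 and Hmgcs1, which makes HMG-CoA, at 311 CPM ± 14.7 against 231 CPM ± 11.2. Interferon-stimulated genes rose in 20 of 29 (24 adjusted over the list alone), with Oasl2, an oligoadenylate synthetase relative, at 142 CPM ± 11.4 against 74.2 CPM ± 18.5. Nrep, a regulator linked to wound repair, fell from 67.3 CPM ± 2.1 to 27.4 CPM ± 2.9, and Smpd3, a neutral sphingomyelinase, rose from 12.2 CPM ± 1.3 to 23.8 CPM ± 0.95.

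Among matrix lists of these cells, 7 of 21 collagens fell and 2 rose (8 and 2 adjusted over the list alone), with Col8a2 (log2 change -0.69, SE 0.12) and Col15a1 (-0.29, SE 0.058). In addition 7 of 20 crosslinking genes rose and 2 fell (8 and 3 adjusted over the list alone), with Lox (0.24) and Plod2 (0.21). Matrix glycoproteins gave 11 rises and 4 falls of 28 (11 and 5 adjusted over the list alone), with Thbs1 (0.39) and Tnc (0.36) higher and Cilp (-0.89) lower. Contractile genes gave 3 rises and 4 falls of 20 (3 and 6 adjusted over the list alone), with Synpo2 (0.25) higher. Angiogenic factors gave 4 rises and 4 falls of 25 (4 and 5 adjusted over the list alone), with Vegfd (0.35, SE 0.042) higher and Angptl4 (-0.39, SE 0.071) lower. Angiogenesis inhibitors gave 7 rises and 1 fall of 17 (9 and 2 adjusted over the list alone), with Adamts1 (0.64) and Thbs1. TGF-beta pathway genes gave 7 rises and 1 fall of 22 (11 and 3 adjusted over the list alone), with Id2 (0.54) and Tgfb2 (0.48). YAP/TEAD targets gave 9 rises and 1 fall of 20 by either adjustment, with Ccn2 (0.41) and Crim1 (0.32). Integrin and focal adhesion genes gave 7 rises of 22 (8 adjusted over the list alone), with the collagen receptor subunit Itga2 (0.91) and Zyx (0.17). ADAM17 substrates gave 10 rises and 2 falls of 32 (11 and 2 adjusted over the list alone), with the Notch ligand Jag1 (0.44) and Nrg1 (0.32). ADAM family genes gave 8 rises of 18 by either adjustment, with Adam23 (0.53), Adam9 (0.31) and Timp3 (0.30), an inhibitor of ADAM17. Ribosomal protein genes gave 6 falls of 25 (10 adjusted over the list alone), with Rps3 (-0.14). In hypoxic myofibroblasts, proteoglycans rose in 4 and fell in 2 of 17 (5 and 2 adjusted over the list alone) and matrix proteases in 4 and 5 of 21 (5 and 8). Protease inhibitors rose in 4 and fell in 3 of 8 (4 and 4 adjusted over the list alone).

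Camera calls that held with an estimated correlation were cholesterol synthesis (3e-23 and 0.029), the ADAM family (1.2e-05 and 0.029) and angiogenesis inhibitors (0.0024 and 0.034). Calls that ended were interferon-stimulated genes (4.4e-16 and 0.24), collagens (0.0031 and 0.6), crosslinking (0.008 and 0.6), TGF-beta (0.017 and 0.09), ADAM17 substrates (0.017 and 0.2), YAP/TEAD (2.5e-05 and 0.18), integrins (0.0078 and 0.18) and ribosomal proteins (6.5e-05 and 0.6). Beyond Adam17 and Nrep (log2 change -1.30, SE 0.063), the largest falls were Bmf (-1.09), a cell death gene, the iron exporter Slc40a1 (-0.94) and Cilp. Rises were led by Nlrc5 (1.05), Zbp1 (1.04), Smpd3 (0.97), Oasl2 (0.93) and Itga2. Of these, Nlrc5 lost its call with length offsets and Zbp1 with only the groups compared. In all, 1945 genes passed, 1288 higher and 657 lower, with 8 and 22 beyond 2-fold. With length offsets 1172 passed, 788 higher and 384 lower.

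In normoxic fibroblasts, Adam17 siRNA raised 13 of 29 interferon-stimulated genes (24 adjusted over the list alone), whose camera call ended with an estimated correlation, with Zbp1, a sensor of Z-form nucleic acids, at 55.4 CPM ± 9.1 (SD, n = 3) against 25.6 CPM ± 0.71 (n = 3). Fth1, the ferritin heavy chain of iron storage, rose by 0.66 on the log2 scale (SE 0.046, adjusted p = 4e-13) among 4 NRF2 and antioxidant genes of 22 that rose (11 adjusted over the list alone), a list whose camera call ended too. Vegfa, the main endothelial growth factor, rose from 277 CPM ± 11.9 to 345 CPM ± 7.9, Timp3 rose by 0.19 on the log2 scale, and Nrep fell from 77.7 CPM ± 4.8 to 37.3 CPM ± 2.6.

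Of the collagens in normoxic fibroblasts 1 rose and 1 fell of 21 (2 and 1 adjusted over the list alone), with Col11a1 (log2 change -0.29) lower. Contractile genes gave 1 rise and 1 fall of 20 by either adjustment. Matrix glycoproteins gave 5 rises of 28 (7 rises and 3 falls adjusted over the list alone), with Tnc (0.38) and Fbln2 (0.25). Crosslinking genes gave 6 rises of 20 (7 rises and 1 fall adjusted over the list alone), with Lox (0.27) and P4ha2 (0.21). Angiogenic factors gave 2 rises and 2 falls of 25 (2 and 3 adjusted over the list alone), with Vegfa (0.32) and Vegfd (0.22) higher and Cxcl12 (-0.22) lower. Protease inhibitors gave 5 rises of 8, HIF targets 5 of 28, glycolysis genes 4 of 20, the unfolded protein response 7 of 25, cholesterol synthesis 5 of 23 and TGF-beta genes 6 of 22 (5, 9, 7, 10, 7 and 9 adjusted over the list alone), with Reck (0.31), Ndrg1 (0.39), Hsp90b1 (0.18), Insig1 (0.28) and Id2 (0.39). ADAM17 substrates gave 4 rises and 2 falls of 32 (5 and 2 adjusted over the list alone), with Prnp (0.29). The ADAM family gave 6 rises of 18 by either adjustment, with Adam23 (0.43) and Adam19 (0.25). In normoxic fibroblasts, proteoglycans rose in 3 and fell in 1 of 17 (4 and 3 adjusted over the list alone) and matrix proteases in 3 and 2 of 21 (3 and 3). Angiogenesis inhibitors rose in 4 and fell in 1 of 17 (5 and 2 adjusted over the list alone). By camera, protease inhibitors (2.5e-05 and 0.041) held with an estimated correlation. Calls that ended were interferon-stimulated genes (4.3e-21 and 0.16), the unfolded protein response (9e-09 and 0.081), NRF2 genes (2.2e-06 and 0.081) and HIF targets (2.2e-05 and 0.14). Further calls that ended were crosslinking (0.00014 and 0.35), cholesterol synthesis (0.00019 and 0.43), glycolysis (0.0002 and 0.35), the ADAM family (0.0079 and 0.16), cell cycle genes, which moved down (0.0079 and 0.53), YAP/TEAD targets (0.039 and 0.53) and the TGF-beta list (0.016 and 0.095), whose median was -0.01 and mean 0.08 for an upward call. The largest rises were Zbp1 (1.11, SE 0.215), Ly6a (1.01), Oasl2 (0.94), Apol9b (0.93) and Smpd3 (0.89). After Adam17, falls were led by Nrep (-1.06, SE 0.069), the imprinted gene Mest, Pkhd1l1 (-0.74) and Serpina3g (-0.65). Of these, Oasl2 lost its call with only the groups compared, and Pkhd1l1 and Serpina3g with length offsets. Apol9b lost its call without the first Adam17 siRNA library (log2 change 0.87) or the third control siRNA library (0.82), and Serpina3g without the first (-0.59) or the third (-0.60) Adam17 siRNA library. In all 712 genes passed, 467 higher and 245 lower, and 456 without the third library with Adam17 siRNA. With length offsets 368 passed, 246 higher and 122 lower.

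In normoxic myofibroblasts, Adam17 siRNA raised cholesterol synthesis genes in 16 of 23 (18 adjusted over the list alone): Insig1 stood at 325 CPM ± 9.6 (SD, n = 3) against 262 CPM ± 0.91 (n = 3) and Hmgcs1 at 423 CPM ± 12.1 against 344 CPM ± 8.4. Nrep fell from 91.1 CPM ± 6.1 to 42.9 CPM ± 2.4 and Smpd3 rose from 19.9 CPM ± 1.1 to 31.4 CPM ± 3.0. Collagens fell in 5 of 21 (7 adjusted over the list alone), with Col6a3 (-0.29) losing its call with length offsets. Timp1 fell by 0.24 on the log2 scale (SE 0.039), from 485 CPM ± 16.2 to 411 CPM ± 9.3. Vegfd rose from 144 CPM ± 2.5 to 189 CPM ± 3.2 among 4 rises and 3 falls of 25 angiogenic factors (6 and 3 adjusted over the list alone), and Sema3c, a guidance factor, fell (-0.44).

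Of further lists in these cells, contractile genes gave 1 rise and 1 fall of 20 (2 and 1 adjusted over the list alone). Matrix glycoproteins gave 7 rises and 2 falls of 28 (8 and 5 adjusted over the list alone), with Thbs1 (log2 change 0.30) and Tgfbi (-0.30). Crosslinking genes gave 6 rises and 2 falls of 20 (7 and 5 adjusted over the list alone), with Plod2 (0.23) and Tgm2 (-0.30). HIF targets gave 7 rises and 2 falls of 28, glycolysis genes 4 rises of 20 and angiogenesis inhibitors 4 rises of 17 (10 and 2, 5, and 5 adjusted over the list alone), with Ndrg1 (0.28), Slc16a3 (0.33) and Adamts1 (0.40). ADAM17 substrates gave 4 rises and 1 fall of 32 by either adjustment, with Cd44 (0.38), Jag1 (0.27) and Cx3cl1 (-0.25). The ADAM family gave 5 rises of 18 (5 rises and 1 fall adjusted over the list alone), with Adam9 (0.21). In normoxic myofibroblasts, proteoglycans rose in 2 and fell in 1 of 17 (2 and 2 adjusted over the list alone) and matrix proteases in 4 and 4 of 21 (5 and 5). Protease inhibitors rose in 3 and fell in 1 of 8 (3 and 2 adjusted over the list alone). Ifit3, the most abundant of the interferon-stimulated genes, stood at 293 CPM ± 92.3 against 274 CPM ± 74.3 (adjusted p = 0.908), and the list had a median log2 change of 0.17. The camera call of cholesterol synthesis (1.9e-21 and 0.047) held with an estimated correlation. Those that ended were collagens (2.1e-05 and 0.52), glycolysis (0.0018 and 0.52), interferon-stimulated genes (0.0038 and 0.84), HIF targets (0.0046 and 0.52), the ADAM family (0.005 and 0.26) and angiogenesis inhibitors (0.015 and 0.16). Rises were led by Ly6a (0.93), Rbm18 (0.74, SE 0.06), Cdo1 (0.72), Smpd3 (0.66) and the G protein regulator Rgs4 (0.66). The falls after Adam17 were led by the nuclear pore gene Nup210 (-1.19), Ano4 (-1.16), Nrep (-1.09) and Bmf (-0.97). Of these, Nup210 lost its call with length offsets. In all 714 genes passed, 419 higher and 295 lower. With length offsets 340 passed, 221 higher and 119 lower. The count was 404 without the second control siRNA library, 474 without the first and 445 without the third library with Adam17 siRNA.

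**Figure D3:**
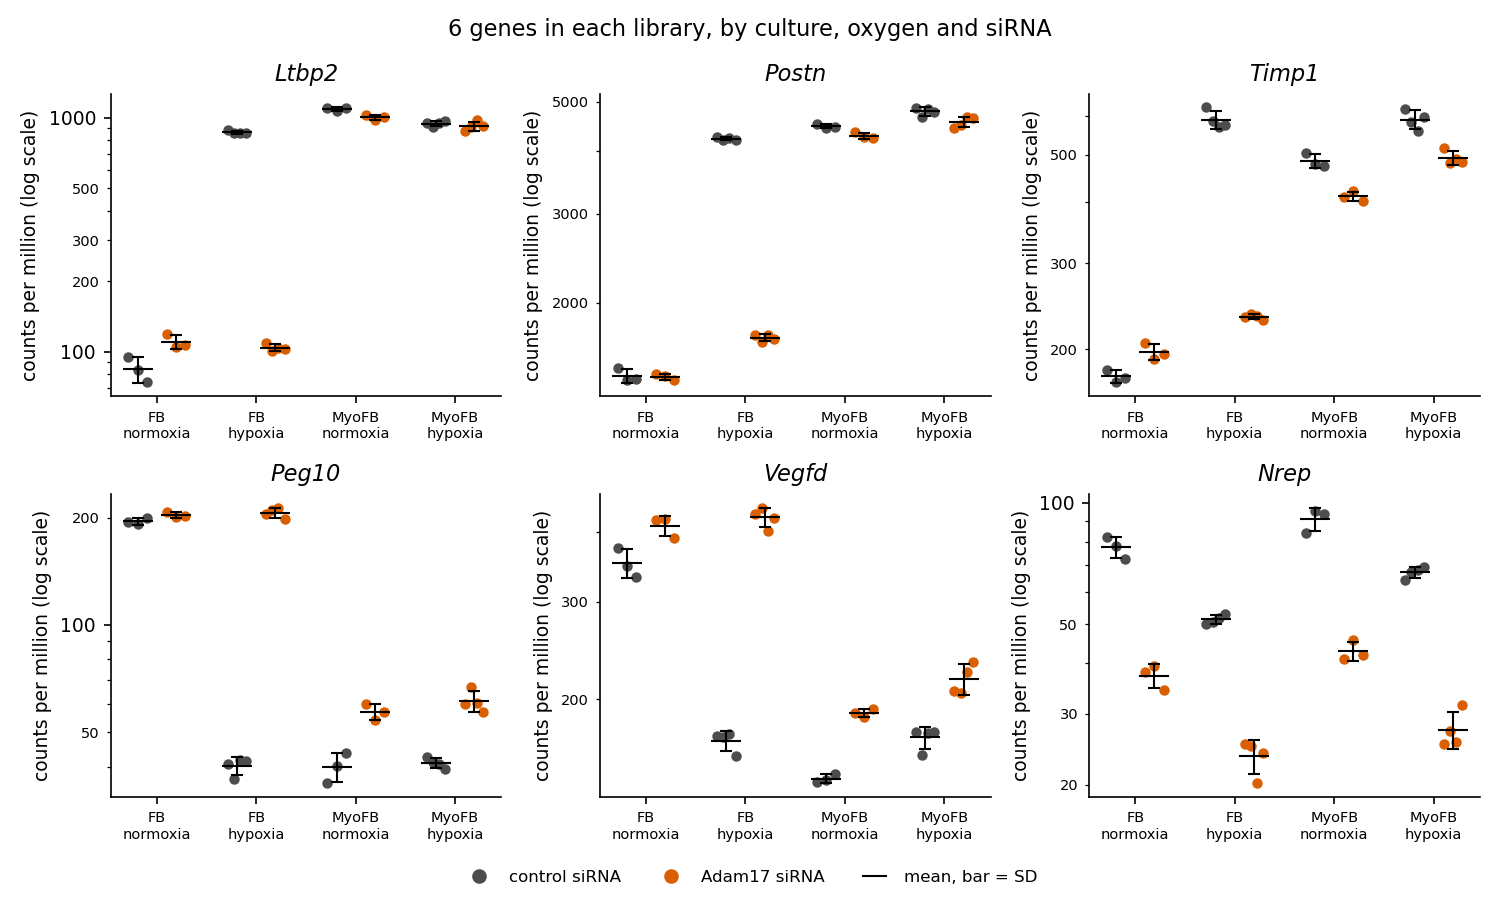
Ltbp2, Postn, Timp1, Peg10, Vegfd and Nrep in CPM (log scale) for each library (points), with the mean and SD of each group (black), by culture (FB fibroblast, MyoFB myofibroblast), oxygen and siRNA. Peg10 was 40.3 CPM in hypoxic control fibroblasts and 195 to 207 CPM in the other 3 fibroblast groups, while Nrep was lower with Adam17 siRNA in all 4 settings.

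Genes that rose or fell in all 4 settings were counted, and the 4 silencing comparisons share no library. In total, 131 rose in all 4 and 49 fell, where 0.23 and 0.045 were expected from the counts alone. Mmp13 (mean log2 change 1.48), Ly6a (1.24), Itga2 (1.07), Smpd3 (0.90), the monocyte chemokine Ccl7 (0.80), the transcription regulator Id2 (0.73) and Fth1 (0.65) rose in all 4. Those that fell included Adam17 (-1.94), Nrep (-1.14), the collagen gene Col9a2 (-0.91), Bmf (-0.83), Cx3cl1 (-0.68), Masp1 (-0.63) and Pdcd10 (-0.61), and the named genes were all chosen from the shared genes after their values were seen. Of the 131 genes, 19 (14.5%), among them Itga2 and Adamts5, carried in their 3′ untranslated region a 7-base word found in 1.3% of all genes. The word was picked in the normoxic comparisons, which in part sets this share. Between the hypoxic and normoxic myofibroblasts 356 genes rose and 179 fell in both settings, with 1 in opposite directions. Between the hypoxic and normoxic fibroblasts 244 rose and 111 fell in both, with 174 in opposite directions. Correlation of log2 changes across genes, which are not independent replicates, was 0.13 for the first pair and 0.05 for the second.

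**Figure D4:**
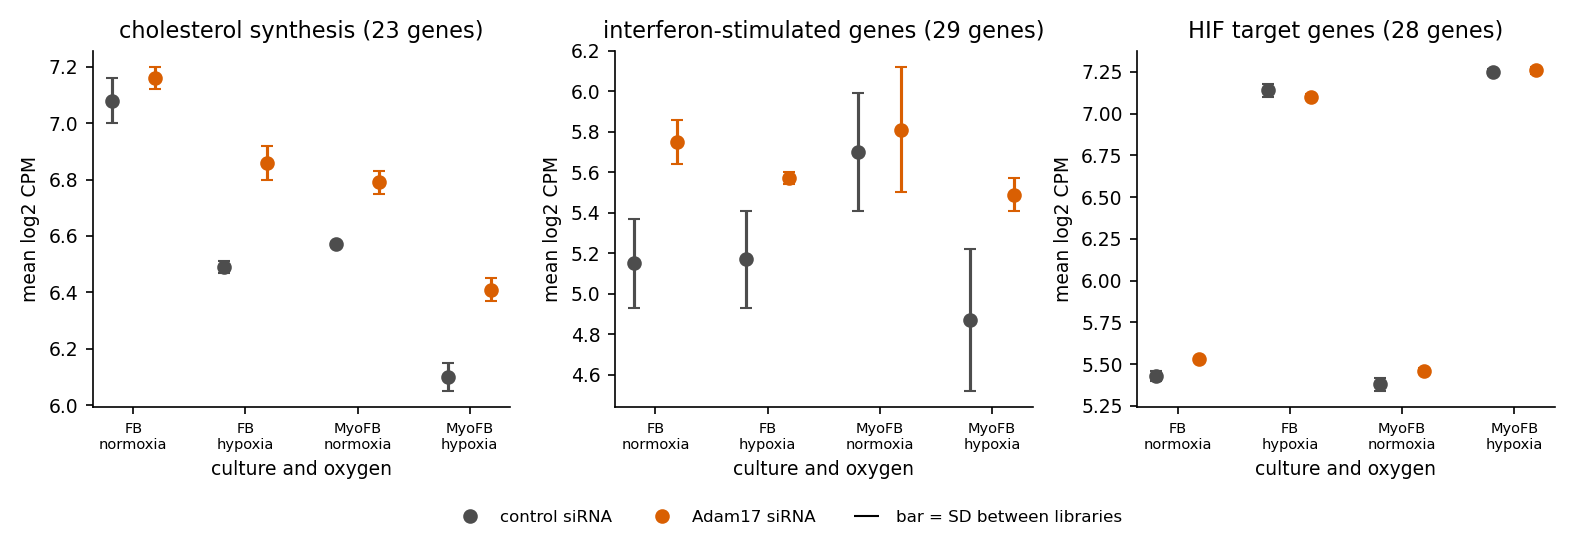
Mean log2 CPM of 23 cholesterol synthesis genes, 29 interferon-stimulated genes and 28 HIF target genes by culture (FB fibroblast, MyoFB myofibroblast), oxygen and siRNA, with bars for the SD between libraries. Cholesterol synthesis genes averaged 6.41 with Adam17 siRNA and 6.10 with control siRNA in hypoxic myofibroblasts, and HIF targets 7.10 to 7.26 in hypoxia and 5.38 to 5.53 in normoxia.

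Whether the effect of Adam17 siRNA depended on oxygen or on the culture was tested as a difference of effects. In fibroblasts, the effect varied by oxygen for Ltbp2 (difference -3.45, SE 0.073), Peg10 (2.30, SE 0.065), Rflnb (-1.69), Postn (-1.30) and Cx3cl1 (-1.89), the 5 genes with the smallest adjusted p (6.48e-27 for Ltbp2). Postn stood at 1428 and 1436 CPM with and without silencing in normoxia and 1707 and 4224 CPM in hypoxia. Another exposure of the hypoxic control dishes stays open. In all 3953 genes passed, 1892 with a more positive and 2061 with a more negative effect in hypoxia. Among them were 20 of 25 genes of the unfolded protein response on the negative side (22 adjusted over the list alone), whose camera call held (1.3e-13 and 0.039). In myofibroblasts edgeR passed 0 genes for the oxygen question, with 1158 at an unadjusted p under 0.05 and 23 by DESeq2. That count was 4 without the fourth hypoxic Adam17 siRNA library and 1, 3 and 3 without the second, the third and the fourth hypoxic control siRNA libraries. Between cultures in hypoxia, Cx3cl1 (1.84), Ltbp2 (3.03), Postn (1.24), Rflnb (1.52) and Fam189a2 (2.30) led 3757 genes with another effect in myofibroblasts than in fibroblasts. In normoxia 13 genes differed between cultures, led by Timp1 (-0.41, SE 0.056), Ltbp2 (-0.51), Igfbp2 (-0.51), Peg10 (0.45) and Selp (-0.50). Of these, Ltbp2 lost its call with only the groups compared and Selp with length offsets. That count was 7 with length offsets, 39 by DESeq2 and 26 without the first control siRNA library of normoxic fibroblasts. Interferon-stimulated genes had a more positive silencing effect in hypoxic than in normoxic myofibroblasts by camera (median difference 0.41, 2.9e-12 and 0.26) and a more negative one in normoxic myofibroblasts than in normoxic fibroblasts (median -0.46, 5.8e-12 and 0.46), and both calls ended with an estimated correlation.

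Hypoxia was tested in control fibroblasts, but another exposure of hypoxic dishes stays open. Slc16a3, the lactate exporter, rose from 17.2 CPM ± 2.1 (SD, n = 3) to 429.8 CPM ± 20.5 (n = 4). Also higher were Bnip3, a mitophagy receptor, from 38.7 CPM ± 2.0 to 467 CPM, and Egln3, a HIF prolyl hydroxylase, from 4.09 CPM ± 0.32 to 66.7 CPM ± 3.7. Vegfa rose from 277 CPM ± 11.9 to 799 CPM ± 10.7. Fgf7 fell from 30.3 CPM ± 0.25 to 6.38 CPM ± 0.31, Vegfd from 352 CPM ± 21.1 to 168 CPM ± 7.1 and the BMP target Id1 from 82.5 CPM ± 6.0 to 9.57 CPM ± 0.90. Postn rose from 1436 to 4224 CPM, Timp1 from 176 CPM ± 4.7 to 589.5 CPM ± 24.7. Col1a1 of type I collagen rose from 9001 CPM ± 499 to 14666 CPM ± 841. With Adam17 siRNA Postn went from 1428 to 1707 and Vegfd from 411 to 425 CPM.

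Of 28 HIF targets 26 rose and 1 fell, and of 20 glycolysis genes 18 rose and 1 fell, by either adjustment, with Pdk1 (log2 change 3.06) and Pfkfb3 (2.71). Collagens gave 15 rises and 3 falls of 21, matrix glycoproteins 17 and 6 of 28 and crosslinking genes 17 and 2 of 20, by either adjustment, with Col6a3 (1.78), Thbs1 (1.34), the prolyl hydroxylase subunit P4ha2 (2.16) and Plod1 (1.76). Contractile genes went both ways, 8 up and 8 down of 20 by either adjustment, with Synpo2 (1.23) and Lmod1 (-1.09). Angiogenic factors gave 6 rises and 14 falls of 25 (7 and 14 adjusted over the list alone), with Angptl4 (1.79) and Pgf (1.36) rising beside Vegfa. Cholesterol synthesis gave 21 falls of 23 (22 adjusted over the list alone), with Hsd17b7 (-1.17) and Insig1 (-0.92). The unfolded protein response gave 22 rises and 2 falls of 25 by either adjustment, with Shmt2 (1.13) and Trib3 (0.98). ADAM17 substrates gave 6 rises and 16 falls of 32 (7 and 16 adjusted over the list alone), with Cx3cl1 (1.95) and Ncam1 (2.64) rising. ADAM family genes gave 6 rises and 7 falls of 18 by either adjustment, with Adam12 (-0.64). EGFR and immediate early genes gave 4 rises and 15 falls of 27 (5 and 15 adjusted over the list alone), with Egr1 (-2.41). The p53 targets gave 5 rises and 14 falls of 19 by either adjustment, with Btg2 (-1.32). Apoptosis genes gave 4 rises and 11 falls of 20, with Bcl2l1 (-1.46). Ribosomal protein genes gave 22 rises of 25 and mitochondrial transcripts 11 falls of 13 by either adjustment. Proteoglycans rose in 8 and fell in 5 of 17 (9 and 5 adjusted over the list alone) and matrix proteases in 6 and 8 of 21 (6 and 10). Protease inhibitors rose in 4 and fell in 2 of 8 and angiogenesis inhibitors in 3 and 7 of 17, by either adjustment. Camera calls that held with an estimated correlation were HIF targets (2.2e-28 and 0.0002), glycolysis (8.2e-23 and 0.0054), crosslinking (1.5e-15 and 0.027), the unfolded protein response (1.5e-12 and 0.024) and cholesterol synthesis (3.5e-15 and 0.043). Calls that ended were collagens (1.8e-06 and 0.28), glycoproteins (2.8e-05 and 0.27), ribosomal proteins (8.1e-05 and 0.49) and mitochondrial transcripts (0.0016 and 0.37). Further calls that ended were p53 targets (0.0094 and 0.055), EGFR genes (0.012 and 0.28) and apoptosis (0.03 and 0.055). The largest rises were Mgarp (5.42, SE 0.204), Ndufa4l2 (4.84, SE 0.142), a mitochondrial protein gene that hypoxia induces, Slc16a3 (4.65), Ccl17 (4.41) and Gipr, with 3 to 6 counts per normoxic and 102 to 169 per hypoxic library. The falls were led by the chemokine Cxcl5 (-3.33), Abca8a (-3.33), Id1 (-3.10), Ccbe1 (-3.10) and the succinate receptor Sucnr1 (-3.08). In all 6868 genes passed, 3591 higher and 3277 lower, with 598 and 435 beyond 2-fold. Over 4706 genes that differed between the normoxic Adam17 siRNA cultures, these hypoxia effects had a slope of 0.65 on that difference across genes, which are not independent replicates, against -0.06 for the hypoxia effects in control myofibroblasts, and neither effect shares a library with that difference. Macrophage and leukocyte markers rose in 8 and fell in 1 of 18 by either adjustment, with Itgam (0.55) higher, and the Y-linked Eif2s3y fell (-0.35).

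In control myofibroblasts, hypoxia raised Slc16a3 from 11.1 CPM ± 0.61 (SD, n = 3) to 388 CPM ± 13.1 (n = 4), Bnip3 from 29.4 CPM ± 0.89 to 517 CPM ± 15.1 and Vegfa from 286 CPM ± 10.8 to 819.8 CPM ± 16.8. Contractile genes fell in 17 of 20 and rose in 2 by either adjustment: Acta2 went from 2762 CPM ± 117 to 1508 CPM ± 75.1. Interferon-stimulated genes fell in 25 of 29 (27 adjusted over the list alone), with Ifit3 from 274 CPM ± 74.3 to 93.7 CPM ± 35. Cell cycle genes rose in 21 of 30 and fell in 3 (21 and 4 adjusted over the list alone), with the proliferation antigen Mki67 at 22.1 CPM ± 0.56 and 37.2 CPM ± 1.6. Postn rose by 0.10 on the log2 scale, from 4468 CPM ± 40.8 to 4782 CPM ± 89.7.

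Of 28 HIF targets 27 rose and of 20 glycolysis genes 18, by either adjustment, with Egln3 (log2 change 5.10) and Pfkl (2.94). Collagens gave 11 rises and 4 falls of 21 (12 and 4 adjusted over the list alone), glycoproteins 13 and 6 of 28 and crosslinking genes 13 and 3 of 20, by either adjustment for both, with Col14a1 (0.51), Lama4 (0.50), P4ha2 (2.42) and P4ha1 (1.27). Angiogenic factors gave 11 rises and 4 falls of 25 (11 and 5 adjusted over the list alone), with Angptl4 (2.03), Pgf (1.99) and the peptide hormone Apln (1.90). Angiogenesis inhibitors gave 1 rise and 9 falls of 17 by either adjustment, with Thbs2 (-0.55). TGF-beta genes gave 2 rises and 14 falls of 22, with Id1 (-1.52) and Tgfb2 (-0.87), by either adjustment. Cholesterol synthesis gave 21 falls of 23, with Dhcr7 (-0.64), by either adjustment. ADAM17 substrates gave 4 rises and 18 falls of 32 by either adjustment, with Ncam1 (1.27) and Csf1 (-0.69). The ADAM family gave 4 rises and 9 falls of 18 (4 and 10 adjusted over the list alone), with Adam19 (0.57). YAP/TEAD targets gave 4 rises and 11 falls of 20 (4 and 12 adjusted over the list alone), with Tead1 (-0.61). Proteoglycans rose in 5 and fell in 4 of 17 and matrix proteases in 7 and 7 of 21, by either adjustment. Protease inhibitors rose in 4 and fell in 2 of 8 (4 and 3 adjusted over the list alone). Camera calls held with an estimated correlation for HIF targets (2.8e-48 and 5.3e-07), glycolysis (3.6e-38 and 0.00029), TGF-beta (0.00027 and 0.0081) and cholesterol synthesis (2e-16 and 0.039). Calls ended for interferon-stimulated genes (2.8e-09 and 0.3), contractile genes (9e-08 and 0.1), crosslinking (2.6e-06 and 0.15), cell cycle (0.00011 and 0.3), ribosomal proteins (0.00011 and 0.49), YAP/TEAD (0.00039 and 0.19) and ADAM17 substrates (0.001 and 0.059). Further calls that ended were collagens (0.0043 and 0.49), the unfolded protein response (0.0043 and 0.3), angiogenesis inhibitors (0.0049 and 0.052), p53 targets (0.0063 and 0.059), angiogenic factors (0.015 and 0.15), integrins (0.023 and 0.19) and mitochondrial transcripts (0.023 and 0.49). Rises were led by Ndufa4l2 (6.81, SE 0.173), Mgarp (6.39), Gpr35 (5.52), Ankrd37 (5.45) and Gipr, with 0 to 1 counts per normoxic and 209 to 323 per hypoxic library. Falls were led by Nlrc5 (-1.66, SE 0.248), Rsad2 (-1.60), Ifit3 (-1.54), Id1 and Abca8a. In all 5631 genes passed, 2692 higher and 2939 lower, with 349 and 66 beyond 2-fold.

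The hypoxia response was then compared within the Adam17 siRNA cultures. In fibroblasts 27 of 28 HIF targets and 18 of 20 glycolysis genes rose and in myofibroblasts 27 and 18, by either adjustment, with Slc16a3 at 343 CPM ± 8.6 (SD, n = 4) against 21.1 CPM ± 0.92 (n = 3) in the first and 396 CPM ± 14.6 against 14 CPM ± 0.58 in the second. Cholesterol synthesis fell in 19 of 23 in each (20 and 19 adjusted over the list alone), with Insig1 (-0.50 in fibroblasts, -0.69 in myofibroblasts). Contractile genes fell in 15 and 17 of 20 and rose in 2 (16 and 17 falls adjusted over the list alone), with Acta2 (-0.67 and -0.90). Collagens rose in 14 and 13 of 21 and fell in 4 and 2 (15 and 14 rises adjusted over the list alone), with Col14a1 (0.57 and 0.54) and Col18a1 (0.69 and 0.53). Crosslinking genes rose in 13 of 20 in each by either adjustment, with P4ha2 (2.06 and 2.32), and fell in 2 in myofibroblasts. Angiogenic factors gave 8 rises and 4 falls in fibroblasts and 11 rises and 8 falls in myofibroblasts of 25 (10 and 4, and 11 and 8, adjusted over the list alone), with Vegfa (1.21 and 1.38) and Apln (1.24 and 1.48). ADAM17 substrates fell in 15 of 32 and rose in 4 in each (16 falls adjusted over the list alone in each, with 5 and 4 rises), with Tnfrsf1b (-0.50 and -0.61). The p53 targets fell in 14 and 11 of 19 by either adjustment, with Pmaip1 (-0.92 and -0.90). Cell cycle genes rose in 4 and 19 of 30 (4 and 20 adjusted over the list alone), with Ccne2 (0.79 and 1.27). Within Adam17 siRNA fibroblasts, matrix glycoproteins rose in 13 and fell in 3 of 28 (14 and 3 adjusted over the list alone) and proteoglycans in 3 and 5 of 17 by either adjustment. Matrix proteases rose in 3 and fell in 4 of 21 and protease inhibitors in 4 and 1 of 8, by either adjustment. There, angiogenesis inhibitors rose in 3 and fell in 5 of 17 (3 and 6 adjusted over the list alone) and ADAM family genes in 7 and 2 of 18 by either adjustment. Within Adam17 siRNA myofibroblasts, matrix glycoproteins rose in 11 and fell in 4 of 28 (13 and 4 adjusted over the list alone) and proteoglycans in 5 and 3 of 17 by either adjustment. Matrix proteases rose in 4 and fell in 3 of 21 (3 and 3 adjusted over the list alone) and protease inhibitors in 3 and 2 of 8 by either adjustment. In these, angiogenesis inhibitors rose in 2 and fell in 7 of 17 by either adjustment and ADAM family genes in 4 and 7 of 18 (4 and 8 adjusted over the list alone). Postn stood at 1707 CPM ± 27 against 1428 CPM ± 20.8 in fibroblasts and 4553 CPM ± 108 against 4279 CPM ± 61.0 in myofibroblasts.

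Camera calls that held with an estimated correlation in fibroblasts with Adam17 siRNA were HIF targets (5e-53 and 2.3e-06), glycolysis (5.5e-42 and 0.0001), crosslinking (1.4e-14 and 0.034) and p53 targets (8.1e-10 and 0.0001). Calls that ended there were cholesterol synthesis (1.6e-14 and 0.05), contractile genes (2.2e-06 and 0.15), mitochondrial transcripts (2.1e-06 and 0.15), collagens (1.2e-05 and 0.36), oxidative phosphorylation (7.6e-05 and 0.37), glycoproteins (0.0021 and 0.4), ADAM17 substrates (0.011 and 0.14) and the unfolded protein response (0.018 and 0.41). In myofibroblasts HIF targets (1.3e-52 and 8.6e-07), glycolysis (3.8e-40 and 0.00012), cholesterol synthesis (8.1e-16 and 0.035), TGF-beta (0.002 and 0.031) and p53 targets (0.0018 and 0.034) held. The calls of crosslinking (1.4e-08 and 0.12), contractile genes (9e-09 and 0.094), cell cycle (2.4e-05 and 0.29), collagens (0.00099 and 0.44), interferon-stimulated genes (0.0018 and 0.55), mitochondrial transcripts (0.0018 and 0.42), the unfolded protein response (0.0023 and 0.32), glycoproteins (0.0034 and 0.43), ADAM17 substrates (0.01 and 0.16) and YAP/TEAD targets (0.017 and 0.43) ended. The largest rises in fibroblasts were Mgarp (log2 change 5.49), Ndufa4l2, Gpr35 (4.61), Egln3 (4.45, SE 0.072) and Gipr, with 0 to 1 counts per normoxic and 270 to 400 per hypoxic library. Falls were led by Angptl7 (-1.89), Rerg (-1.75), Egr1 (-1.68), Abca8a (-1.52) and Gm28048 (-1.45), which lost its call with only the groups compared. In myofibroblasts rises were led by Ndufa4l2 (6.62), Mgarp (6.10), Egln3 (5.15, SE 0.08), Gpr35 (5.07) and Gipr, with 1 to 5 and 125 to 224 counts, and falls by Abca8a (-1.61), Angptl7 (-1.44), Ccbe1 (-1.32), Id1 (-1.31) and Gsta3 (-1.27). In all 4484 genes passed in fibroblasts, 2322 higher and 2162 lower, and 4997 in myofibroblasts, 2542 higher and 2455 lower. Over the 4 hypoxia comparisons 1084 genes rose and 829 fell in all, where 18 and 16 were expected, and the correlation of log2 changes across genes, which are not independent replicates, was 0.40 to 0.62.

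Whether hypoxia acted differently in the 2 control cultures was tested as a difference of effects, with 4369 genes past the threshold, 2005 more positive and 2364 more negative in myofibroblasts. Rflnb (difference -1.90, SE 0.05), Notch4 (-2.00), Cx3cl1 (-1.95), Postn (-1.46) and Ltbp2 (-3.57) had the smallest adjusted p, 1.6e-28 for Rflnb, each with a more positive hypoxia effect in fibroblasts. Angiogenic factors gave 14 more positive and 1 more negative effect of 25 by either adjustment, and their camera call held with an estimated correlation (1.3e-06 and 0.028). Cell cycle genes gave 25 more positive and 1 more negative effect of 30 and the unfolded protein response 1 and 20 of 25, by either adjustment. Interferon-stimulated genes gave 19 more negative effects of 29 and contractile genes 13 of 20 (22 and 14 adjusted over the list alone). The camera calls of these 4 lists ended with an estimated correlation. In order they were 3.7e-09 and 0.15, 3e-10 and 0.061, 1.6e-06 and 0.47, and 7.8e-08 and 0.15. Another exposure of the hypoxic control fibroblasts, part of each difference, stays open.

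**Figure D5:**
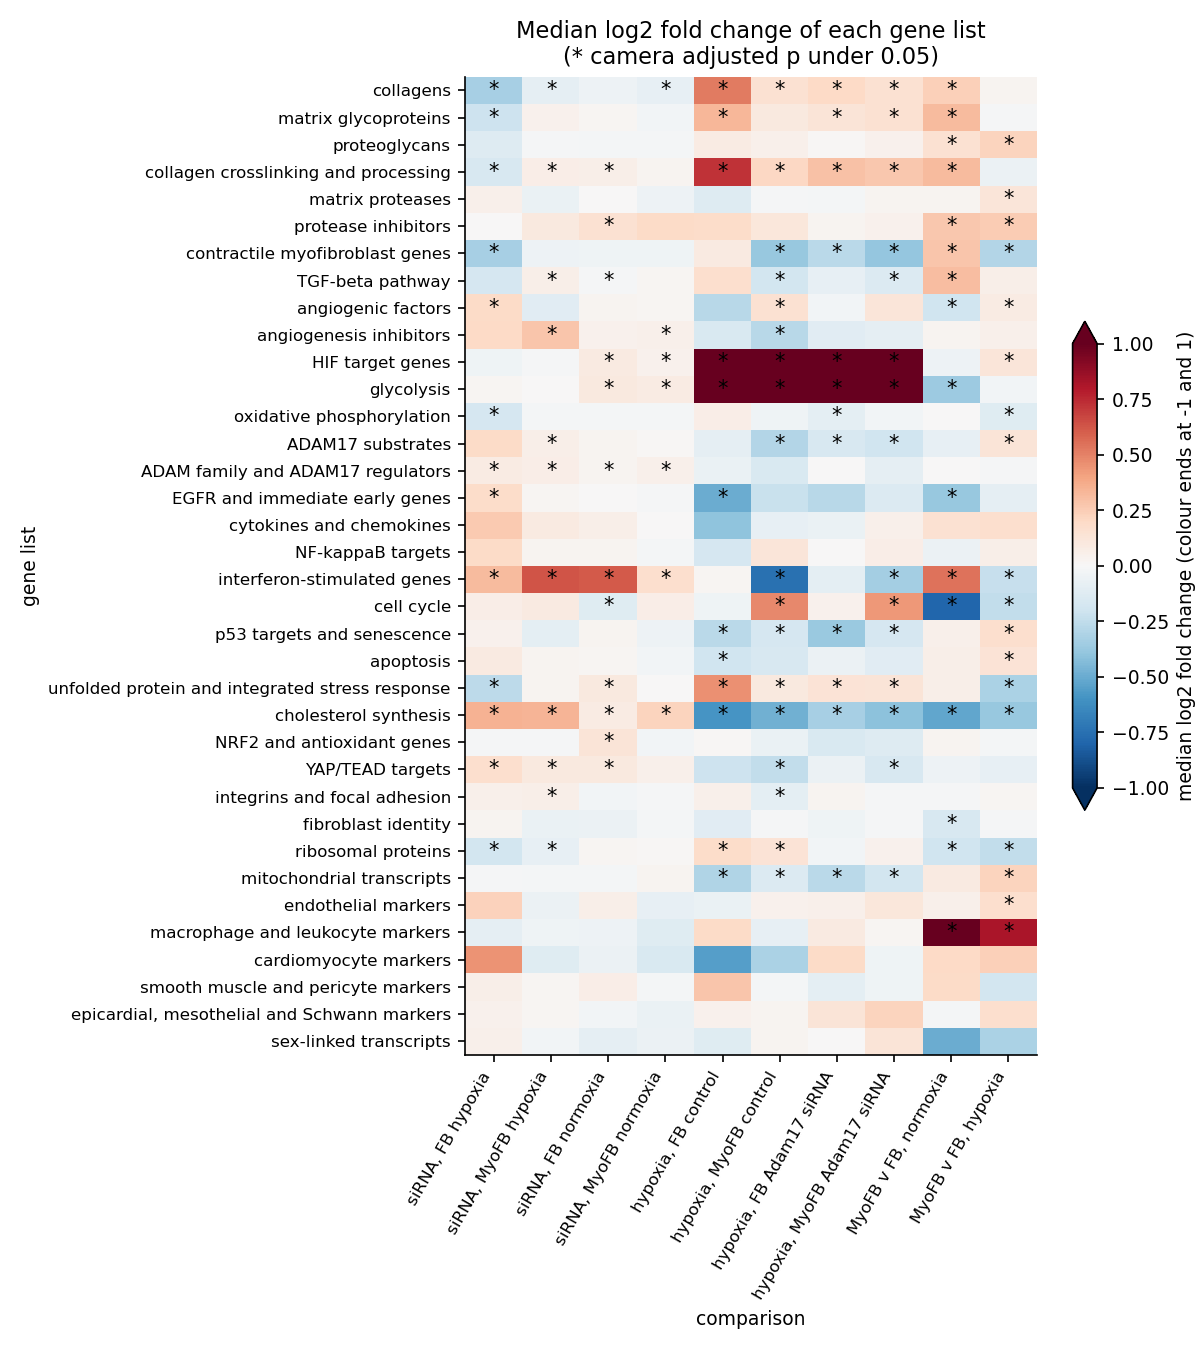
Median log2 fold change of each gene list (vertical axis) in the 10 comparisons of 2 groups (horizontal axis; FB fibroblast, MyoFB myofibroblast), with colours that end at -1 and 1 and a star where camera with a preset correlation gave an adjusted p under 0.05. HIF targets had medians of 1.39 to 1.74 in the 4 hypoxia comparisons, and cholesterol synthesis genes medians of 0.08 to 0.35 with Adam17 siRNA and -0.59 to -0.33 with hypoxia.

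Myofibroblasts were compared with fibroblasts among the normoxic control cultures. Postn stood at 4468 CPM ± 40.8 (SD, n = 3) in myofibroblasts and 1436 CPM ± 44.7 (n = 3) in fibroblasts, Timp1 at 485 CPM ± 16.2 and 176 CPM ± 4.7, and the transcription factor Meox1, which is tied to fibroblast activation, at 19.2 CPM ± 1.3 and 2.97 CPM ± 0.49. Adm was lower in myofibroblasts, at 105 CPM ± 3.3 against 277 CPM ± 18.2, as were Vegfd and Fgf7 (log2 differences -1.29 and -1.23). Mki67 was lower, at 22.1 CPM ± 0.56 against 50.4 CPM ± 5.0, among 29 of 30 cell cycle genes by either adjustment. Macrophage and leukocyte markers were higher in 16 of 18 and lower in 1 by either adjustment, with Adgre1 at 16.2 CPM ± 0.66 against 5.81 CPM ± 0.67 and C1qa at 47.6 CPM ± 1.3 against 18.8 CPM ± 1.8. All 4 tested Y-linked genes were lower, Kdm5d by a log2 difference of -0.57. In the same comparison 6 of 16 endothelial markers were higher and 4 lower, with Vwf (1.14) and Kdr (-0.98).

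Collagens were higher in 14 and lower in 4 of 21 (15 and 4 adjusted over the list alone), matrix glycoproteins in 17 and 7 of 28 (18 and 7) and crosslinking genes in 13 and 4 of 20 (14 and 5), with Col8a2 (log2 difference 1.86), Eln (1.58) and Loxl2 (0.90). Contractile genes were higher in 10 and lower in 3 of 20 (11 and 4 adjusted over the list alone), with Tpm1 (0.67) and Cnn1 (0.64). TGF-beta genes were higher and lower in 13 and 4 of 22 by either adjustment, with Tgfb1 (1.11) and Pmepa1 (1.21). Angiogenic factors were higher in 5 and lower in 11 of 25 (6 and 13 adjusted over the list alone), with Angpt2 (-1.36). Cholesterol synthesis genes were lower in 22 of 23 (23 adjusted over the list alone), with Mvd (-0.81). ADAM17 substrates went both ways, 12 higher and 11 lower of 32 by either adjustment, with Cx3cl1 (2.16) and the EGFR ligand Hbegf (1.18). So did the ADAM family, 7 and 7 of 18 (7 and 8 adjusted over the list alone), with Adam12 (-0.80). Interferon-stimulated genes were higher in 16 of 29 (20 adjusted over the list alone), with Ifi44 (1.05). EGFR and immediate early genes were lower in 16 and higher in 2 of 27 (17 and 2), with Dusp4 (-0.94), and glycolysis genes were lower in 13 and higher in 2 of 20 (14 and 2), with Pfkl (-0.62). Proteoglycans were higher in 9 and lower in 3 of 17 by either adjustment and matrix proteases in 8 and 8 of 21 (9 and 9 adjusted over the list alone). Protease inhibitors were higher in 5 and lower in 2 of 8 and angiogenesis inhibitors in 7 and 6 of 17, by either adjustment. The camera calls of TGF-beta (0.0026 and 0.038), cell cycle (3.4e-18 and 0.038), cholesterol synthesis (3.4e-18 and 0.038) and macrophage markers (6.7e-11 and 0.049) held with an estimated correlation. Those of ribosomal proteins (2.9e-08 and 0.33), crosslinking (2e-07 and 0.17), glycolysis (6.9e-06 and 0.2), collagens (2.6e-05 and 0.33), glycoproteins (0.00015 and 0.32), interferon-stimulated genes (0.00016 and 0.69) and angiogenic factors (0.0011 and 0.089) ended. Further calls that ended were EGFR genes (0.0014 and 0.2), contractile genes (0.0044 and 0.42), protease inhibitors (0.0079 and 0.14), fibroblast identity (0.015 and 0.33) and proteoglycans (0.03 and 0.32). The largest rises were Adamts8 (4.45, SE 0.27), Padi4 (3.75), Ccl17 (3.73), Ltbp2 (3.69, SE 0.057) and Lrrn1, with 1 to 2 counts per fibroblast and 89 to 151 per myofibroblast library. The falls were led by Cxcl5 (-4.41, SE 0.175), Prkar2b (-2.51), Peg10 (-2.28), Cxcl1 (-2.07) and Bub1, with 146 to 234 counts per fibroblast library and 0 in 2 and 36 in 1 myofibroblast library. Bub1 lost its call without the first (-3.50) or the third (-3.45) myofibroblast library, and without the second it stood at 0 in the others. In all 5198 genes passed, 2670 higher and 2528 lower, with 460 and 296 beyond 2-fold.

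Among the hypoxic control cultures, Postn was higher in myofibroblasts by a log2 difference of 0.18, 4782 CPM ± 89.7 (SD, n = 4) in myofibroblasts and 4224 CPM ± 26.0 (n = 4) in fibroblasts, while Timp1 did not pass, at 590.1 CPM ± 26.2 and 589.5 CPM ± 24.7. Acta2 was lower in myofibroblasts, 1508 CPM ± 75.1 against 2338 CPM ± 59.1, among 13 lower and 1 higher of 20 contractile genes by either adjustment. Macrophage markers were higher in 16 of 18 (17 adjusted over the list alone), with Adgre1 at 16.8 CPM ± 0.34 against 8.19 CPM ± 1.6, and the 4 Y-linked genes were lower, Kdm5d by a log2 difference of -0.46. Vwf was higher (0.96) and Kdr lower (-0.83) among endothelial markers.

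Collagens were higher in 4 and lower in 4 of 21 (5 and 4 adjusted over the list alone) and glycoproteins in 7 and 7 of 28 by either adjustment, with Col1a2 (log2 difference -0.25), Comp (0.87) and Tnc (-0.73). Angiogenic factors were higher in 8 and lower in 2 of 25 (9 and 2 adjusted over the list alone), with Angpt1 (0.73) and Fgf2 (0.70). ADAM17 substrates were higher in 12 and lower in 4 of 32 (13 and 4 adjusted over the list alone), with Vcam1 (0.63) and Cd44 (-0.64). The ADAM family was higher and lower in 5 and 6 of 18 by either adjustment, with Adam8 (0.43). Cholesterol synthesis genes were lower in 19 of 23 (21 adjusted over the list alone), with Hmgcr (-0.60). The unfolded protein response was lower in 20 of 25 (20 lower and 1 higher adjusted over the list alone), with Chac1 (-0.61). Ribosomal proteins were lower in 24 of 25 by either adjustment, with Rps2 (-0.38). Cell cycle genes were lower in 20 of 30 (22 adjusted over the list alone), with Mcm2 (-0.57), and p53 targets were higher in 13 and lower in 1 of 19 (15 and 1), with Pmaip1 (1.17). Crosslinking genes were higher in 4 and lower in 9 of 20 and proteoglycans in 9 and 4 of 17, by either adjustment. Matrix proteases were higher in 11 and lower in 1 of 21 (11 and 2 adjusted over the list alone) and protease inhibitors in 5 and 1 of 8 by either adjustment. Angiogenesis inhibitors were higher in 6 and lower in 1 of 17 by either adjustment. The camera calls of the unfolded protein response (8.8e-16 and 0.011), cholesterol synthesis (9.6e-17 and 0.032), macrophage markers (3.4e-15 and 0.018) and p53 targets (1.3e-06 and 0.0041) held with an estimated correlation. Those of ribosomal proteins (8.8e-16 and 0.16), cell cycle (2e-06 and 0.17), contractile genes (2.9e-05 and 0.17), HIF targets (0.00028 and 0.17) and ADAM17 substrates (0.026 and 0.17) ended. Further calls that ended were oxidative phosphorylation (1.8e-05 and 0.19), mitochondrial transcripts (0.00021 and 0.19), matrix proteases (0.00053 and 0.094), protease inhibitors (0.004 and 0.094), interferon-stimulated genes (0.0056 and 0.58), proteoglycans (0.018 and 0.19), angiogenic factors (0.037 and 0.19), apoptosis (0.037 and 0.094) and endothelial markers (0.043 and 0.19). Rises were led by the macrophage genes Fcrls (2.23, SE 0.104) and Cx3cr1 (2.21), Igfbp2 (1.37), Bmx (1.23) and Fgf23, with 52 to 81 counts per fibroblast and 146 to 221 per myofibroblast library. Falls were led by Bex4 (-1.14), Nnat (-1.06), Osr1 (-1.05), Psat1 (-0.99, SE 0.059) and Siglecg (-0.98). In all 4932 genes passed, 2312 higher and 2620 lower, with 190 and 25 beyond 2-fold.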

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

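The tests of the hypoxic control fibroblasts and of the Y-linked genes were chosen after the result was seen, those of siRNA seed words and the splits of the libraries before.

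Effects differed between settings in 4 of the 5 tests of a difference. The effect of Adam17 siRNA in fibroblasts depended on oxygen for 3953 genes, with differences of 2.30 for Peg10, -3.45 for Ltbp2, -1.69 for Rflnb, -1.30 for Postn and -1.89 for Cx3cl1. In hypoxia it depended on the culture for 3757 genes, with 1.84 for Cx3cl1, 3.03 for Ltbp2, 1.24 for Postn, 1.52 for Rflnb and 2.30 for Fam189a2. In normoxia it depended on the culture for 13 genes, with -0.41 for Timp1, -0.51 for Ltbp2, -0.51 for Igfbp2, 0.45 for Peg10 and -0.50 for Selp. The effect of hypoxia in controls depended on the culture for 4369 genes, with -1.90 for Rflnb, -2.00 for Notch4, -1.95 for Cx3cl1, -1.46 for Postn and -3.57 for Ltbp2.

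The hypoxic control fibroblasts enter 3 of these differences and carried matrix genes such as Ltbp2 and Postn at levels near those of myofibroblasts. Across genes, which are not independent replicates, their difference from hypoxic Adam17 siRNA fibroblasts had a slope of 0.54 on the myofibroblast against fibroblast difference of normoxic controls, over 5198 genes with no shared library. The tables argue against whole libraries swapped with a myofibroblast group, since the mean of the macrophage markers lay at a position of 0.00 and Y-linked genes at 0.22 between the other fibroblast groups (0) and the myofibroblasts (1), with 0 of the 4 libraries inside the myofibroblast range for either list. That mean joins markers that moved both ways, as 8 of 18 rose and 1 fell with hypoxia in control fibroblasts, and 2 rose and 7 fell with Adam17 siRNA in hypoxic ones. The tables also argue against a mixture with a myofibroblast culture as the whole cause. In CPM between hypoxic Adam17 siRNA fibroblasts (0) and hypoxic control myofibroblasts (1), 300 other genes over 2-fold higher in myofibroblasts in both normoxic comparisons lay at a median of 0.68 (quartiles 0.36 to 0.93), and 16 macrophage markers higher there at 0.16 (-0.03 to 0.22), with Adgre1 at 0.21 and C1qa at 0.20. Y-linked genes, at -0.19 to 0.59, decide nothing, and a mixture behind a smaller part stays open. A hypoxia response of fibroblasts that needs Adam17 may give such a pattern, as silencing in normoxic fibroblasts had a slope of 0.00 on the culture difference of hypoxic Adam17 siRNA cells, but another exposure of these dishes might too. These 2 cannot be told apart, because each group received 1 combination of oxygen and siRNA.

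Genes that changed with Adam17 siRNA in all 4 settings were 131 that rose and 49 that fell. Seed matches were searched as 7-base words in 3′ untranslated regions, picked in normoxic cultures and ranked among 16169 words in hypoxic myofibroblasts. The word that went with higher fold changes ranked 1 in that comparison, which had no part in the choice, so release from seed matches of the control siRNA is a candidate explanation for part of the rises, and 19 of the 131 risers carry it, a share in part set by picking the word in normoxic cultures. The word that went with lower fold changes ranked 18, too low to count as a match of the Adam17 siRNA and too high to exclude it. Its log2 effect there was -0.03, a size at which the search was not tested by simulation. The siRNA sequences were not used here, so direct effects of Adam17 loss and off-target effects of either siRNA stay open.

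Y-linked transcripts were lower in myofibroblast than in fibroblast cultures in all 4 combinations of oxygen and siRNA, with 16 of 16 log2 differences below 0, from -0.25 to -0.59. The TMM scaling factors are argued against by the same comparisons with total counts alone, where the highest of the 4 medians of these genes was -0.28, while a scaling error common to both ways was not tested. A lower share of cells from male animals may explain the pattern, as the labels give a pool of both sexes. The share of male cells was not measured in another way, so a lower expression of these 4 genes in myofibroblasts stays open.

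The libraries of 2 groups were also split in every other way into groups of the same sizes, and the genes past the threshold were counted again. Of 35 splits, the real one led for Adam17 siRNA in hypoxic fibroblasts (5939 against 1 in the highest other) and myofibroblasts (1945 against 218). It led between control cultures in hypoxia (4932 against 14). This leaves chance differences between dishes open. For hypoxia the real split led in control fibroblasts (6868 against 4683) and control myofibroblasts (5631 against 3460). It led in Adam17 siRNA fibroblasts (4484 against 2482) and myofibroblasts (4997 against 3084). Splits of 4 against 3 can nearly reverse the groups and so give high counts. The 10 splits of 3 against 3 are too few for a share under 0.05. There the real and highest other counts were 712 and 1 for Adam17 siRNA in normoxic fibroblasts, 714 and 1 in normoxic myofibroblasts, and 5198 and 0 for myofibroblasts against fibroblasts in normoxia.

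For differences of effects, 60 splits of the libraries of 4 groups were counted. These also break up the effects that are compared. A split that leaves a pair of groups whole counts the effect in 1 setting, so these splits decide nothing about chance here. The real count, the highest other and the splits with at least the real count were 3953, 3731 and 1 for oxygen and silencing in fibroblasts, 3757, 4773 and 3 for culture and silencing in hypoxia, 13, 377 and 9 for both in normoxia, and 4369, 6429 and 3 for culture and hypoxia in controls. For oxygen and silencing in myofibroblasts, edgeR called 0 genes (1158 at an unadjusted p under 0.05 and 23 by DESeq2), against 1229 in the highest other, and all 60 splits gave as many.

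Of 140 groups of 4 libraries over 35 measures, 9 had a library far from the others, and chance gives about 1 in 20 groups, or 7. Replicate 2 of hypoxic control fibroblasts held 18882848 estimated counts, with 22274401 to 22824945 in the others. In hypoxic control myofibroblasts, replicate 2 had Cxcl5 at 2.16 CPM (others 1.27 to 1.34) and Vegfd at 159 CPM (174 to 175), replicate 4 had Slc16a3 at 407 CPM (379.7 to 384), and replicate 3 had Mki67 at 34.9 CPM (37.6 to 38.2). In hypoxic Adam17 siRNA myofibroblasts, replicate 2 had Mmp13 at 1.36 CPM (0.998 to 1.02). In hypoxic Adam17 siRNA fibroblasts, replicate 4 had Oasl2 at 159.6 CPM, below the others, replicate 1 had Meox1 at 4.32 CPM (2.83 to 2.95) and replicate 3 had Hmgcs1 at 458 CPM (399 to 409).

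Transcripts that matched no gene name stayed out of the comparisons, and 406 of 1418 had enough counts for a test. Past the threshold were 27 with Adam17 siRNA in hypoxic fibroblasts and 1 in hypoxic myofibroblasts. With hypoxia, 38 passed in control fibroblasts, 13 in control myofibroblasts, 7 in Adam17 siRNA fibroblasts and 12 in Adam17 siRNA myofibroblasts. Between cultures, 9 passed in normoxia and 12 in hypoxia.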

How the results depend on the processing

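The count that leaves out genes differing between the normoxic control cultures was chosen only after the result was seen, and the other alternatives were fixed before the data were examined. Of 282 counts under alternatives, 248 stayed within 1.5 times the count reported. Over the 8 alternatives that keep all libraries of the groups compared, genes past the threshold with Adam17 siRNA numbered 4757 to 6108 in hypoxic fibroblasts, and with hypoxia 5550 to 6868 in control fibroblasts and 4244 to 5631 in control myofibroblasts. Of 18886 values of named genes, 18088 kept their direction and their side of the threshold, 797 no longer passed, and 1 reversed: Cenpf with hypoxia in Adam17 siRNA fibroblasts fell by 0.24 (-0.24) with length offsets. The cause of these changes was not tested.

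With length offsets, genes past the threshold with Adam17 siRNA numbered 1172 in hypoxic myofibroblasts, 368 in normoxic fibroblasts and 340 in normoxic myofibroblasts, against 1945, 712 and 714, and the difference between cultures in normoxia 7, against 13. DESeq2 gave 39 for that difference, and 23 for oxygen and silencing in myofibroblasts, where edgeR gave 0, no filter beyond 1 count gave 6 and the replicate block gave 6. The cause was not tested. Of 9527 genes not called between the normoxic control cultures, 2393 passed with Adam17 siRNA in hypoxic fibroblasts and 3059 with hypoxia in control fibroblasts. All 14725 genes gave 5939 and 6868.

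Leaving out 1 library at a time gave 456 to 598 genes with Adam17 siRNA in normoxic fibroblasts, the lowest without the third Adam17 siRNA library. In normoxic myofibroblasts it gave 404 to 541, with 404 without the second control siRNA library, and 474 and 445 without the first and the third Adam17 siRNA libraries. Oxygen and silencing in myofibroblasts gave 0 to 4, with 4 without the fourth hypoxic Adam17 siRNA library, and 1, 3 and 3 without the second, the third and the fourth hypoxic control siRNA libraries. Culture and silencing in normoxia gave 10 to 26, the highest without the first control siRNA library of normoxic fibroblasts. The cause was not tested.

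With an estimated correlation, the gene lists past the threshold numbered 0, 3, 1 and 1 with Adam17 siRNA in hypoxic fibroblasts, hypoxic myofibroblasts, normoxic fibroblasts and normoxic myofibroblasts. With hypoxia they numbered 5 in control fibroblasts, 4 in control myofibroblasts, 4 in Adam17 siRNA fibroblasts and 5 in Adam17 siRNA myofibroblasts, and between cultures 4 in normoxia and 4 in hypoxia. Fry, which asks another question, gave 27 lists with Adam17 siRNA in hypoxic fibroblasts, and with hypoxia 32, 29, 23 and 26 in the order above.

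The replicate numbers were checked for pairing. Over 90 same-numbered pairs, deviations from the group means correlated across genes at -0.076 to 0.098, with 0 of the pairs over 0.1, and 5 of 28 libraries correlated best with a library of their own number, so the numbers were not taken to pair samples. Apart from the 6 genes above, the replicate block moved no count of genes by over 1.5 times. Simulated changes of 1.5-fold were recovered in 83.6% of genes for hypoxic and 77.6% for normoxic fibroblasts, so smaller changes can be missed at this depth and number of libraries.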
